A study of Homo sapiens with 6 samples.

How the data were processed

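RNA sequencing was run on WM3248, a human cell line grown from a primary melanoma. In all, 3 libraries came from cells transfected with a commercial negative control siRNA (the siNC group, n = 3) and the other 3 from cells transfected with an siRNA against PPARGC1A (the siPGC1a group, n = 3). Per the labels, both siRNAs were used at 30 nM with a lipid reagent, RNA was taken 48 h after transfection, and libraries were made with a stranded poly(A) kit and sequenced as single reads. The labels did not say whether the 3 libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The sequence of either siRNA was not given in the sources used here.

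The deposited values were FPKM, which the authors had computed per gene and per library. STAR, Picard, featureCounts and DESeq2, with the hg19 build, are named per the submitters' processing notes, without versions or roles. The strand setting of the read counting was not given in the sources used here. The table held 57688 rows of gene symbols, of which 26707 were at 0 in every library. In 27 rows the symbol had been turned into a date, 2 symbols stood on more than 1 row, and 0 genes of the mitochondrial genome were listed, so mtDNA-encoded transcripts were not analysed here.

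Depth was recovered from the FPKM values, since a gene's values step by what 1 read is worth. With exon lengths from GENCODE v29 (55001 symbols matched), the steps of short miRNA genes gave 25180000 to 26440000 reads per library. Among values of at most 20 reads, 93.3 to 93.8% came out whole within 0.1 read, against 20.0% by chance. The summed FPKM lay between 229001.4 and 236267.6 per library, and 23842 to 24738 genes were above 0. The reference annotation is of another genome build than the table, so it was used for lengths, sequences and neighbours and no coordinates are given.

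Genes with a mean FPKM of at least 1 over the 6 libraries were tested, with PPARGC1A tested regardless, which gave 12020 genes. Values were taken as log2(FPKM + 1) and compared with limma 3.58.1 in R 4.3.3 (limma-trend, two-sided, no replicate block), with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are siPGC1a minus siNC on the log2(FPKM + 1) scale, which understates the change of low genes. Levels are mean FPKM ± SD (n = 3 per group). For single genes an exact two-sided permutation test of the 6 values was added, and 3 against 3 cannot give a p below 0.1. Libraries of a group were compared first, and none was a copy of another: the chi-square statistic per degree of freedom of recovered reads was 2.18 to 7.23 within groups and 34.9 to 47.0 between groups.

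The gene lists, the named genes and the other settings, except those named below as later additions, were fixed before the data were examined. There were 36 lists, covering oxidative phosphorylation (OXPHOS), the TCA cycle, fatty acid oxidation, mitochondrial biogenesis, mitochondrial ribosomal proteins, mtDNA-encoded proteins, antioxidant defence, glycolysis, hypoxia, melanocyte differentiation, the dedifferentiated melanoma state, integrins, extracellular matrix, TGF-beta with BMP and ID targets, Wnt targets, MAPK output, S phase, G2/M, p53 targets, apoptosis, the integrated stress response, the unfolded protein response, heat shock, cholesterol synthesis, fatty acid synthesis, lysosome and autophagy, interferon, NF-kappaB and cytokines, MHC class I, cytosolic ribosomal proteins, histones, immediate early genes, and markers of keratinocytes, fibroblasts, endothelium and immune cells. Some genes stand on more than 1 list. Lists with at least 5 measured members (32) were tested with limma's camera, which compares a list with the other genes, at a preset inter-gene correlation of 0.01 with Benjamini-Hochberg adjustment over lists. Intervals of list medians came from 2000 bootstrap draws of the members, and those of lists that lost their call were added after seeing the data. The mtDNA, keratinocyte, endothelial and immune lists had fewer measured members and are given as values.

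The named genes were PPARGC1A, the 10 largest rises and 10 largest falls past the threshold with no overlap between groups, the 3 members with the smallest adjusted p in the direction of each called list and the 1 in the other direction, up to 2 members past the threshold of each list not called, the most abundant marker of each other cell type, and PPARGC1B, ESRRA, TFAM and MITF. A few genes that this rule takes are not reported here. A gene outside this rule is said to be chosen after its values were seen. Genes with near-identical copies, among them the HLA genes, HSPA8, RPS2, RPLP0, TIMM23, SDHA and the metallothioneins, are uncertain because the counting may have split or dropped shared reads. Of the 119 named genes, 24 have exons overlapping a tested gene on the other strand and are uncertain for the unstated strand setting, including LIPA, ARL2BP, CDK2, CCND1, FEN1, SOD2, IER3 and ESRRA.

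On simulated data with the real means and spreads (12020 genes drawn independently, 198 of them changed), the fit recovered 87.9% of genes changed 1.25-fold and 100% of those changed 1.5-fold or 2-fold, and 6.9% of its calls were unchanged genes. The real data gave 5782 calls, so these shares need not hold for them. The alternatives tried were another pseudocount, no filter and a stricter one, 2 other scalings, the replicate number as a block, each library left out, sample weights, a robust prior, an estimated correlation, fry and ranks. Limma-voom on the recovered reads, and the list tests without genes carrying certain 3' UTR words, were chosen after seeing the data. A scan of 7-base words in the 3' UTRs of 10666 genes was run in Python 3.11.15 with numpy 2.4.6, as a regression of the fold change on the presence of each word with UTR length, base composition and expression as covariates, against 100 permutations of the genes. In simulated data a planted word ranked first.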

Results

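WM3248 melanoma cells were profiled by RNA sequencing 48 h after transfection with a control siRNA (siNC, 3 libraries) or an siRNA against PPARGC1A (siPGC1a, 3 libraries), which encodes PGC1-alpha, a coactivator of mitochondrial gene transcription. Each library held between 25180000 and 26440000 reads. The comparison asks which transcripts differ once PPARGC1A is targeted. The first principal component of the log2 values held 74.4% of the variance and separated the groups.

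PPARGC1A was lower in every siPGC1a library. Its level was 0.932, 1.04 and 0.947 FPKM in the siNC libraries and 0.4, 0.354 and 0.413 FPKM in the siPGC1a libraries. The means were 0.974 ± 0.06 and 0.389 ± 0.031 FPKM (SD, n = 3), so that 60.1% of the transcript was lost (log2 fold change -0.51, SE 0.066, limma adjusted p = 0.000235). These values rest on 260 to 290 reads per siNC library and 97 to 117 per siPGC1a library. The exact permutation p was 0.1, the smallest that 3 against 3 can give. PPARGC1B, the paralog, stood at 0.644 ± 0.071 and 0.642 ± 0.041 FPKM (n = 3), below the filter, with an exact permutation p of 1. ESRRA, a nuclear receptor partner of PGC1-alpha, was at 13.1 ± 0.67 and 13.7 ± 0.997 FPKM (n = 3, limma adjusted p = 0.4). TFAM, which packages mitochondrial DNA and activates its transcription, rose from 7.69 ± 0.519 to 10.4 ± 0.586 FPKM (n = 3, limma adjusted p = 0.000454). MITF, the master regulator of melanocytes, fell from 7.24 ± 0.133 to 5.52 ± 0.261 FPKM (n = 3, limma adjusted p = 0.000334).

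**Figure D1:**
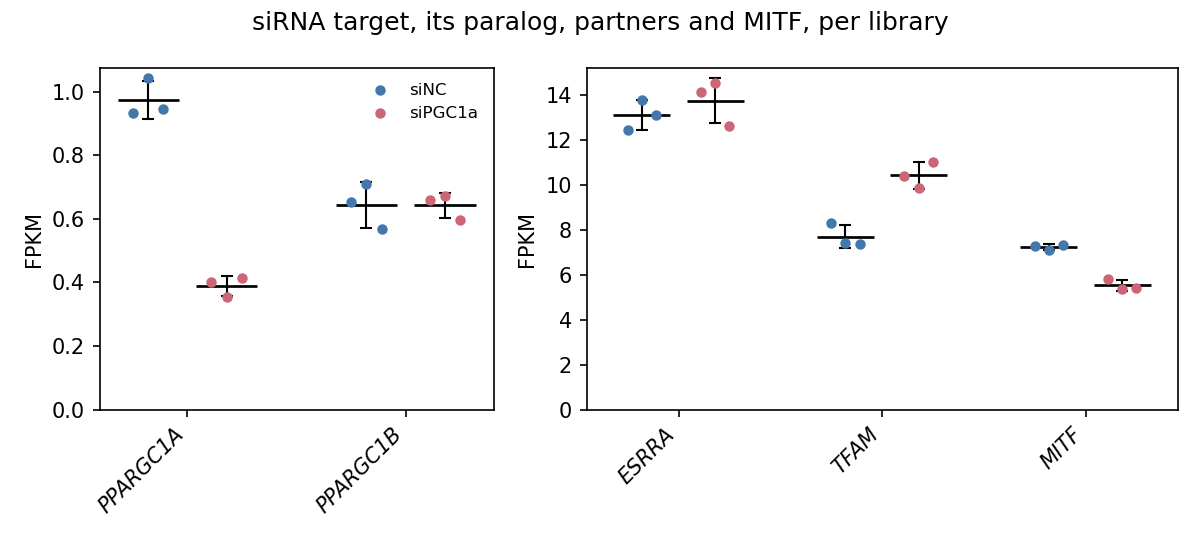
FPKM of PPARGC1A, PPARGC1B, ESRRA, TFAM and MITF in each library (points, 3 per group), with the group mean (bar) and SD (error bars). The 3 siPGC1a values of PPARGC1A lie at 0.354 to 0.413 FPKM, below all siNC values, and PPARGC1B has overlapping groups.

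On the log2(FPKM + 1) scale the 5 largest rises were those of cytokine genes. CXCL8, a neutrophil chemokine, rose 5.86-fold, from 2.45 ± 0.181 to 14.4 ± 1.06 FPKM, and IL1A, a cytokine released on cell damage, rose 4.47-fold, from 4.87 ± 0.165 to 21.8 ± 1.56 FPKM (n = 3; limma adjusted p = 6.87e-08 for each). IL11 rose 6.42-fold, CXCL1 4.17-fold and IL24 3.44-fold in mean FPKM, as did MAFF, a small Maf transcription factor (3.94-fold), and MRGPRX4, CEMIP, SERPIND1 and SYTL5 at 2.81-fold to 3.32-fold. Among the largest falls, MMP2, a gelatinase, fell from 180.9 ± 3.48 to 65.3 ± 2.53 FPKM (n = 3, limma adjusted p = 6.87e-08). LIPA (lysosomal lipase), ARL2BP, FSTL1, ALCAM, RNASE1, BOK, IFI27 and SOSTDC1 fell to ratios of 0.311 to 0.451. The annotated 3' UTR of 7 of these 9 genes, all but IFI27 and SOSTDC1, holds the 6-base word ACACCT, as does that of 2 of the 10 largest rises, IL11 and SERPIND1. Among genes with a searched 3' UTR the word was held by 48.4% of the lower genes, 22.6% of the higher genes and 28.9% of all that were not lower.

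**Figure D2:**
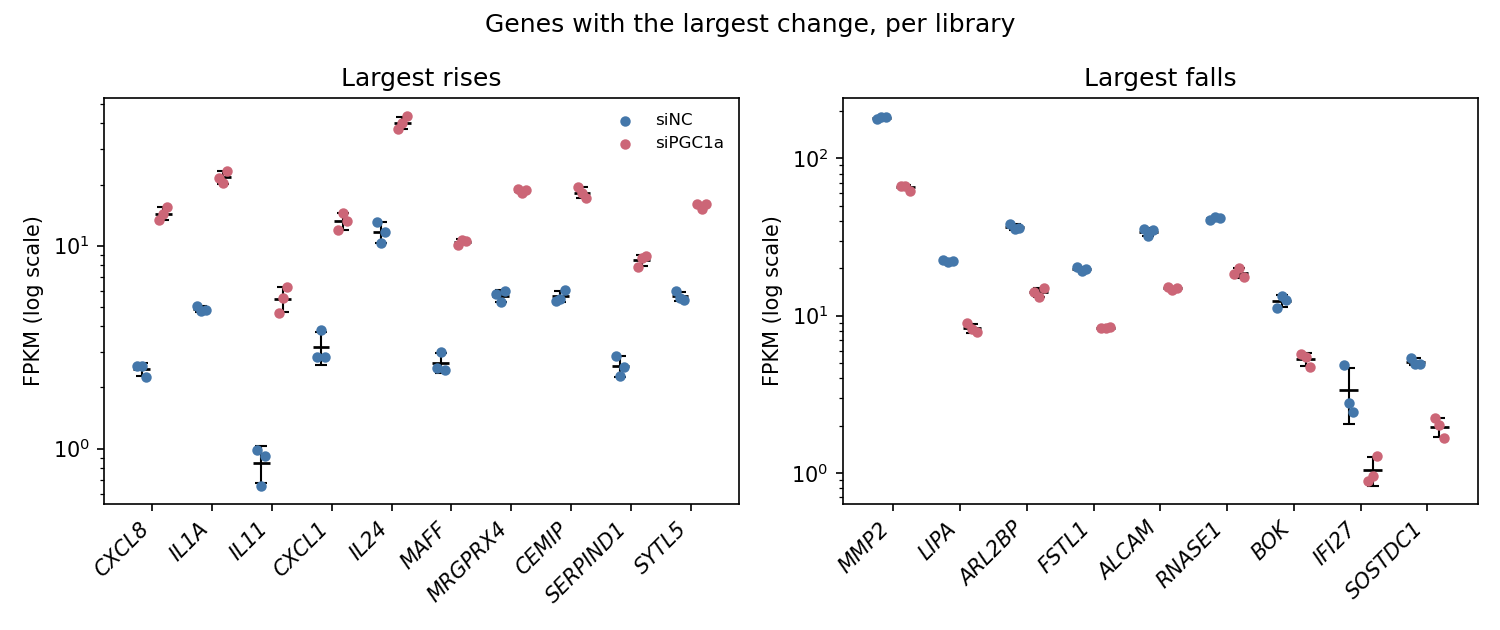
FPKM (log scale) of the 10 genes with the largest rise and of 9 of those with the largest fall in each library (points, 3 per group), with the group mean (bar) and SD (error bars). CXCL8 moves from 2.45 to 14.4 FPKM and MMP2 from 180.9 to 65.3 FPKM, and the groups do not overlap for any gene shown.

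Across the transcriptome, 5782 of 12020 genes (48.1%) passed the limma threshold. Of these 3075 were higher and 2707 lower in siPGC1a, and 6238 did not pass. Most changes were small: the median size among called genes was 0.26 on the log2 scale, 703 called genes differed at least 1.5-fold in mean FPKM, 38 rose and 16 fell by at least 1 on the log2(FPKM + 1) scale. The 3 values of either group lay wholly above those of the other for 6878 genes (57.2%), against 10% by chance.

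Of the 32 gene lists tested with camera, 21 passed at the preset correlation, 13 higher and 8 lower. With an estimated inter-gene correlation 0 of these calls held (adjusted p = 0.186 at lowest), although 8 lists had an unadjusted p under 0.05, and regroupings that mix the groups gave 3 to 14 called lists. The counts of members below rest on limma, gene by gene. Of the 21 lists, 14 kept their camera call under the other settings that could test them, with an adjusted p of at most 0.0352, and the 7 that did not are named with the setting. The ranges of a list's adjusted p below are over camera settings with the preset correlation. Fry, which asks whether a list moved on balance and does not compare it with other genes, called 20 of the 21 (not G2/M, adjusted p = 0.126) and 5 that camera did not: mitochondrial biogenesis (0.00914), antioxidant (0.00247), dedifferentiated (0.0222), lysosome (0.00198) and histones (0.00604). One such setting left out genes whose 3' UTR holds ACACCT or GTCTTC, called the 3' UTR words hereafter, and also genes without a searched 3' UTR. Of the 5279 genes it kept, 1839 were higher and 886 lower by limma. Camera there compared each list with genes that lean higher, which works against a higher call. A higher call lost in that setting need therefore not be due to the words. The lean does not account for lower calls lost there, though fewer members were left to test. Of the list members named below by rule, not already named above and with a searched 3' UTR, 19 of the 43 that fell hold ACACCT there and 24 do not, and 11 of the 44 that rose hold it and 33 do not. The 19 are CS, ACADS, PDK1, P4HA2, BNIP3, ITGA2, COL1A1, COL1A2, POSTN, ID1, ID3, BTG2, VLDLR, PDIA4, CANX, ELOVL1, OAS3, ICAM1 and HLA-C, and the 11 are MRPS7, SLC7A11, TIMP3, TNFRSF19, IER3, RRM2, AEN, MCL1, LIF, EGR3 and TWIST1.

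**Figure D3:**
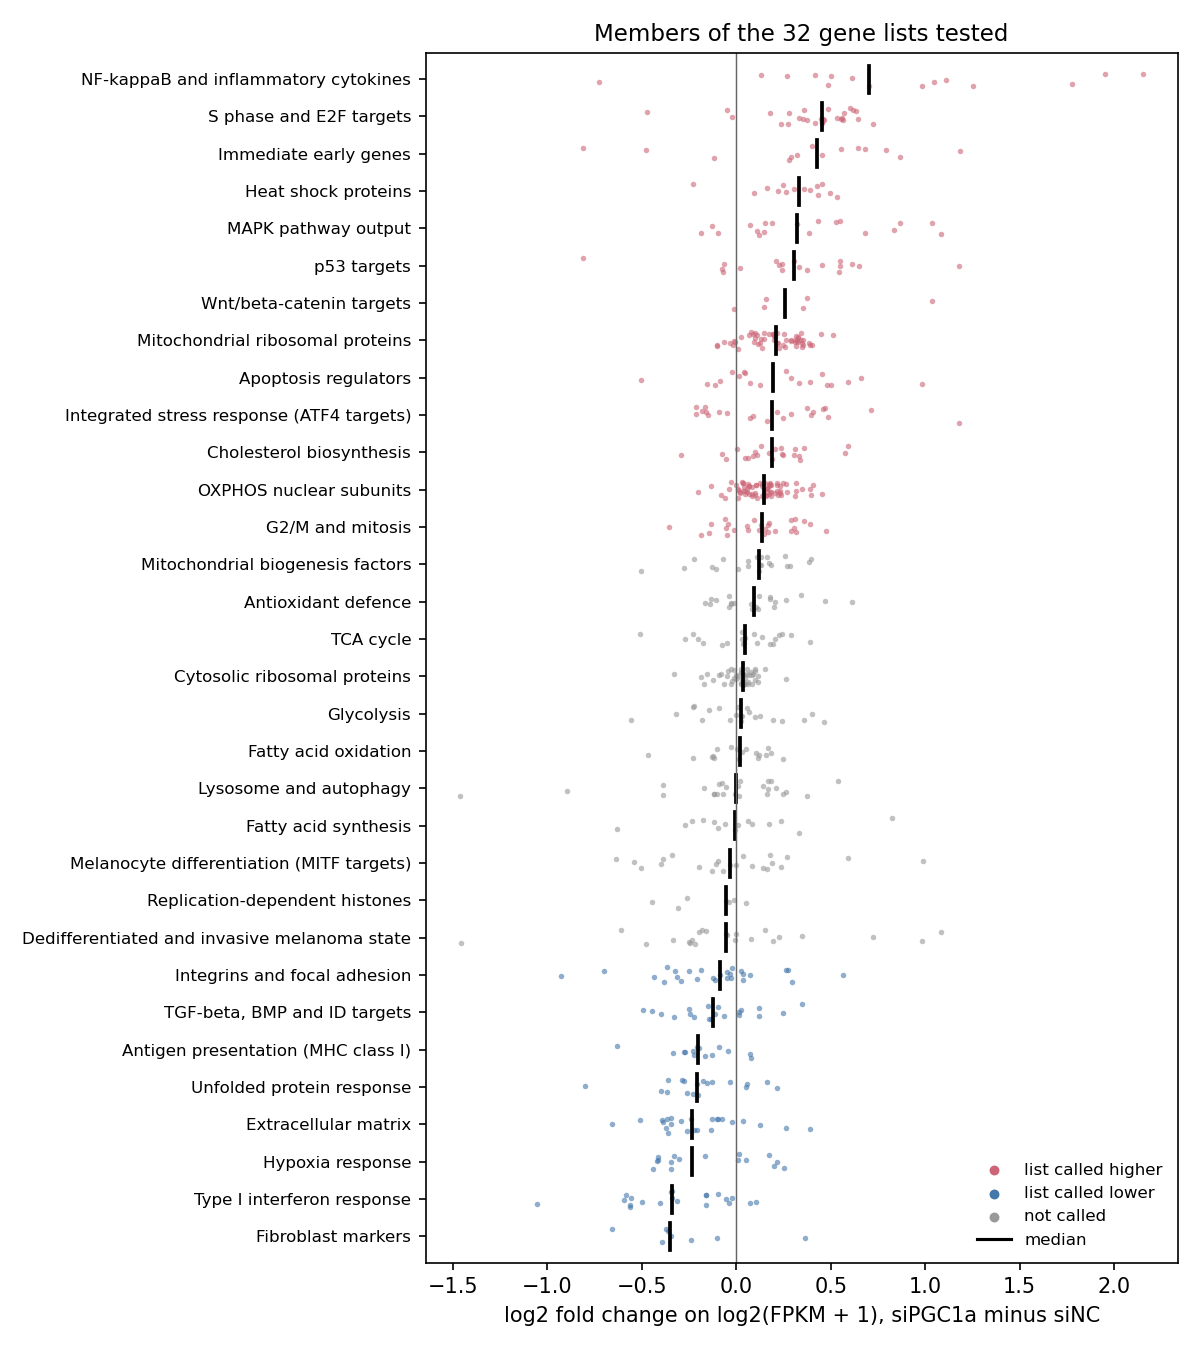
Log2 fold change on log2(FPKM + 1), siPGC1a minus siNC, of the measured members (points) of the 32 lists, with the list median (bar). Red and blue mark lists called higher (13) or lower (8) by camera at a preset correlation, none of them called with an estimated one, and grey the others. Medians run from -0.35 (fibroblast markers) to 0.70 (NF-kappaB and cytokines).

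The NF-kappaB and cytokine list rose, with 14 of 15 measured members higher, 1 lower and 0 not past the threshold (14 and 1 adjusted over the list alone; camera adjusted p = 4.58e-08, adjusted p = 0.186 with an estimated correlation). Besides CXCL8 and IL1A, LIF, a cytokine of the IL6 family, went from 14.4 to 32.3 FPKM. ICAM1, an adhesion receptor, was the member that fell, from 137.9 to 83.0 FPKM, and its 3' UTR holds the word ACACCT at 4 places. Among immediate early genes 11 of 14 rose, 2 fell and 1 did not pass (11 and 3 adjusted over the list alone; camera adjusted p = 0.00171, adjusted p = 0.186 with an estimated correlation). EGR3 rose 4.07-fold to 2.89 FPKM, NR4A1 1.81-fold and IER3 1.61-fold, whereas BTG2, an antiproliferative gene, fell to a ratio of 0.553. This call ended at a stricter filter (adjusted p = 0.129) and without genes carrying the 3' UTR words (adjusted p = 0.0903), in a range of 2.14e-06 to 0.129 over settings. The list median was 0.43 over 14 members (bootstrap 95% interval 0.28 to 0.66), 0.43 over the 8 left by that filter (-0.48 to 0.62) and 0.45 over the 7 without the words (-0.12 to 0.79). MAPK pathway output rose, with 14 of 19 members higher, 2 lower and 3 not past (15 and 2 adjusted over the list alone; camera adjusted p = 4.13e-05, adjusted p = 0.186 with an estimated correlation). CCND1, the G1 cyclin, rose from 72.8 ± 0.612 to 150.6 ± 0.545 FPKM, FOSL1, an AP-1 subunit, rose from 25.2 to 54.5 FPKM, and ETV5 fell from 20.9 to 18.2 FPKM.

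Lists of p53 targets, apoptosis regulators, heat shock proteins and the integrated stress response were called higher at the preset correlation. Of 19 measured p53 targets, 14 rose, 1 fell and 4 did not pass (14 and 1 adjusted over the list alone; camera adjusted p = 0.000299, adjusted p = 0.186 with an estimated correlation). GDF15, a stress-induced cytokine, rose from 48.4 ± 2.83 to 110.7 ± 6.02 FPKM, the death receptor TNFRSF10B from 54.7 to 86.6 FPKM and the nuclease AEN from 15.8 to 23.5 FPKM, and the member that fell was BTG2. Apoptosis regulators gave 10 higher, 1 lower and 9 not past of 20 (10 and 1 adjusted over the list alone; camera adjusted p = 0.0136, adjusted p = 0.193 with an estimated correlation). Members of opposite roles rose. BIRC3 (2.09-fold), MCL1 (1.59-fold) and BCL2A1 (1.56-fold), which restrain apoptosis, led, and BIRC2, which does so too, rose as well. APAF1, BBC3, BAX, BIK and PMAIP1, which promote it, were also among the rises, and BMF, which promotes it too, fell to a ratio of 0.656. BIRC2, APAF1, BBC3, BAX, BIK and PMAIP1 were chosen after their values were seen. Heat shock proteins gave 13 higher and 1 lower of 14 (13 and 1 adjusted over the list alone; camera adjusted p = 4.13e-05, adjusted p = 0.193 with an estimated correlation), led by HSPA8 (228.5 to 309.0 FPKM), HSPH1 and DNAJB1. CRYAB, the lens small heat shock protein, fell from 7.20 to 6.01 FPKM, a call lost without siNC replicate 3 (adjusted p = 0.0666), without siPGC1a replicate 1 (0.0573) and without a filter (0.082), in a range of 0.00254 to 0.082. The integrated stress response list had 12 members higher, 6 lower and 4 not past of 22 (12 and 6 adjusted over the list alone; camera adjusted p = 0.0351, adjusted p = 0.336 with an estimated correlation). CEBPB rose 1.70-fold and the amino acid transporter SLC7A5 1.38-fold, and VLDLR fell to a ratio of 0.835. Its call ended on ranks, at a stricter filter, with quantile scaling, with sample weights and without genes carrying the words (adjusted p of 0.0532 to 0.114, in a range of 0.0101 to 0.114). Its median was 0.19 over 22 members (bootstrap 95% interval -0.09 to 0.39) and 0.22 over the 13 without the words (-0.05 to 0.41).

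Cell cycle genes of the S phase gave the smallest camera p. Of 28 measured S phase and E2F targets, 24 rose, 1 fell and 3 did not pass (25 and 1 adjusted over the list alone; camera adjusted p = 1.07e-09, adjusted p = 0.186 with an estimated correlation). RRM2, a ribonucleotide reductase subunit, rose from 12.1 ± 0.35 to 20.6 ± 0.952 FPKM, the flap nuclease FEN1 from 34.0 to 52.8 FPKM and the chromatin assembly factor CHAF1A from 9.31 to 14.2 FPKM, and CCNE2 fell to 1.53 FPKM, a ratio of 0.611. Of 28 G2/M and mitosis genes 14 rose, 2 fell and 12 did not pass (14 and 3 adjusted over the list alone; camera adjusted p = 0.0482, adjusted p = 0.661 with an estimated correlation). AURKA rose 1.40-fold, AURKB 1.33-fold and CDC25C 1.34-fold, and ANLN fell to a ratio of 0.776. The G2/M call ended without siNC replicate 2 (adjusted p = 0.164), without siPGC1a replicate 3 (0.131) and in 4 other settings (0.147 to 0.363), in a range of 0.00221 to 0.363. The Wnt list of 17 genes had a median of 0.26, and of 0.03 to 0.28 over other settings. Of its 6 measured members 5 rose, 0 fell and 1 did not pass (5 and 0 adjusted over the list alone, camera adjusted p = 0.0056, adjusted p = 0.186 with an estimated correlation). The rises included CCND1, which also stands on the MAPK list, and TNFRSF19 (53.4 to 68.6 FPKM). CTNNB1, which encodes beta-catenin itself, rose as well (44.1 to 57.4 FPKM). Replication-dependent histones were not called, with 0 higher, 3 lower and 4 not past of 7 (0 and 3 adjusted over the list alone; camera adjusted p = 0.156). HIST1H2AC fell from 23.7 to 19.6 FPKM and HIST1H4H from 1.91 to 1.35 FPKM. A poly(A) kit would miss histone transcripts without a poly(A) tail, and only 7 of the 15 listed histones were measured. These values therefore cannot tell how histone transcripts as a whole moved.

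The lists of OXPHOS subunits and mitochondrial ribosomal proteins were called higher at the preset correlation. Of 75 measured OXPHOS subunits 37 rose, 1 fell and 37 did not pass (39 and 2 adjusted over the list alone; camera adjusted p = 3.3e-05, adjusted p = 0.454 with an estimated correlation). The complex III subunit UQCR10 rose from 80.7 ± 1.74 to 110.9 ± 4.59 FPKM, and NDUFA8 and NDUFAB1 of complex I rose from 48.4 to 60.4 FPKM and from 50.9 to 67.5 FPKM. The list median was 0.14 on the log2 scale. SDHA fell from 1.77 to 1.41 FPKM, a call lost in 6 settings, without siNC replicate 2 (adjusted p = 0.0904), siNC replicate 3 (0.0515), siPGC1a replicate 1 (0.0694) and siPGC1a replicate 3 (0.059) among them, in a range of 0.00306 to 0.0904. Of 58 mitochondrial ribosomal protein genes 40 rose, 0 fell and 18 did not pass (41 and 0 adjusted over the list alone; camera adjusted p = 2.18e-07, adjusted p = 0.297 with an estimated correlation), with MRPL39 at 36.9 and 53.2 FPKM, MRPS7 at 17.5 and 23.5 FPKM and MRPS30 at 5.73 and 7.54 FPKM. Members of these 2 lists are short, with a median transcript length of 1388 bases against 3428 for the tested genes.

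With the settings as reported, camera did not call the mitochondrial biogenesis, TCA cycle, fatty acid oxidation, glycolysis or antioxidant lists. Mitochondrial biogenesis factors had 8 members higher, 3 lower and 11 not past of 22 (8 and 3 adjusted over the list alone; camera adjusted p = 0.16, but 0.042 without genes carrying the 3' UTR words, in a range of 0.042 to 0.304), with TFAM and the import channel gene TIMM23 (27.6 to 36.4 FPKM) higher and PPARGC1A lower. TCA cycle genes gave 8 higher, 5 lower and 9 not past of 22 (8 and 5 adjusted over the list alone; camera adjusted p = 0.493). CS, citrate synthase, fell from 30.0 ± 0.122 to 20.7 ± 0.309 FPKM, with ACACCT at 2 places in its 3' UTR, and PC, pyruvate carboxylase, rose from 14.6 to 19.5 FPKM. Fatty acid oxidation gave 5 higher, 3 lower and 10 not past of 18 (5 and 3 adjusted over the list alone; camera adjusted p = 0.776), with ACADS at a ratio of 0.701 and ETFB at 1.21, and its median was above 0 and its mean below 0. Glycolysis gave 6 higher, 5 lower and 11 not past of 22 (7 and 5 adjusted over the list alone; camera adjusted p = 0.754). HK2, a hexokinase, rose from 22.3 to 31.1 FPKM and PDK1, which restrains pyruvate entry into the TCA cycle, fell from 4.24 to 2.56 FPKM. Antioxidant genes gave 10 higher, 3 lower and 9 not past of 22 (10 and 3 adjusted over the list alone; camera adjusted p = 0.146, but 0.0118 without a filter, in a range of 0.0118 to 0.566), with SOD2 up 1.69-fold and SLC7A11, the cystine transporter, up 1.74-fold. Of 16 hypoxia response genes 4 rose, 9 fell and 3 did not pass (4 and 9 adjusted over the list alone; camera adjusted p = 0.0298, adjusted p = 0.193 with an estimated correlation). NDRG1, P4HA2 and BNIP3 fell to ratios of 0.729, 0.782 and 0.736, and CA9, carbonic anhydrase 9, rose 1.17-fold. This call ended without genes carrying the 3' UTR words, where the median went from -0.23 to 0.09 (adjusted p = 0.392, in a range of 0.00348 to 0.392).

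Melanocyte differentiation genes went both ways, with 6 higher, 6 lower and 11 not past of 23 (7 and 7 adjusted over the list alone; camera adjusted p = 0.527). DCT, a pigment enzyme, fell from 393.9 ± 11.2 to 253.3 ± 12.4 FPKM and CDK2 rose from 16.1 to 32.9 FPKM. The dedifferentiated and invasive list was split as well, with 7 higher, 11 lower and 5 not past of 23 (7 and 11 adjusted over the list alone; camera adjusted p = 0.31), from MMP2 among the falls to FOSL1 among the rises.

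The matrix, integrin and TGF-beta lists were called lower at the preset correlation. Of 24 extracellular matrix genes 3 rose, 14 fell and 7 did not pass (3 and 16 adjusted over the list alone; camera adjusted p = 0.000299, adjusted p = 0.234 with an estimated correlation). COL5A2 fell from 282.2 ± 1.39 FPKM to a ratio of 0.702, LAMB1 from 174.6 to 137.2 FPKM and COL1A2 from 3.04 to 1.56 FPKM, and TIMP3, a metalloproteinase inhibitor, rose from 961.1 to 1153 FPKM. Fibroblast markers, some of which stand on this list, were called lower too, with 6 of 8 measured ones lower and 1 higher (camera adjusted p = 0.00943, adjusted p = 0.186 with an estimated correlation). Of 27 integrin and focal adhesion genes 4 rose, 13 fell and 10 did not pass (4 and 13 adjusted over the list alone; camera adjusted p = 0.0184, adjusted p = 0.454 with an estimated correlation). ITGA4 fell from 101.2 ± 5.45 to 52.7 ± 3.33 FPKM, ITGA2 to a ratio of 0.564 and ITGA5 to 0.737, and ZYX rose from 23.1 to 34.7 FPKM. This call ended without siPGC1a replicate 3 (adjusted p = 0.0723, in a range of 0.00316 to 0.0723). TGF-beta, BMP and ID targets gave 2 higher, 8 lower and 10 not past of 20 (3 and 8 adjusted over the list alone; camera adjusted p = 0.0498, adjusted p = 0.198 with an estimated correlation), with SNAI2, ID3 and ID1 at ratios of 0.693, 0.705 and 0.749. This call ended in 10 settings, 4 of them leaving out siNC replicate 2 (adjusted p = 0.0557) or 3 (0.0657), or siPGC1a replicate 2 (0.0653) or 3 (0.0664), in a range of 0.042 to 0.56. Without genes carrying the 3' UTR words its median went from -0.12 over 20 members (bootstrap 95% interval -0.24 to 0.02) to -0.06 over 7 (-0.15 to 0.25; adjusted p = 0.56).

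The interferon, MHC class I and unfolded protein response lists were called lower at the preset correlation. Of 21 type I interferon response genes 0 rose, 13 fell and 8 did not pass (0 and 14 adjusted over the list alone; camera adjusted p = 0.000467, adjusted p = 0.336 with an estimated correlation). IFI27 went from 3.36 ± 1.3 to 1.05 ± 0.214 FPKM, with siNC replicate 1 at 4.85 FPKM, OAS3 from 6.55 to 4.09 FPKM and STAT2 from 14.1 to 10.9 FPKM. Of 14 MHC class I genes 0 rose, 9 fell and 5 did not pass (0 and 10 adjusted over the list alone; camera adjusted p = 0.00171, adjusted p = 0.297 with an estimated correlation). The peptide-trimming enzyme ERAP1 fell from 16.4 to 10.3 FPKM, and HLA-C and HLA-B, whose reads may be shared with related genes, fell to ratios of 0.791 and 0.827. Unfolded protein response genes gave 2 higher, 13 lower and 3 not past of 18 (2 and 13 adjusted over the list alone; camera adjusted p = 0.000553, adjusted p = 0.198 with an estimated correlation). PDIA4, a disulfide isomerase with ACACCT in its 3' UTR, fell from 339.8 ± 6.34 to 194.9 ± 5.77 FPKM, the chaperone CANX from 142.8 to 110.8 FPKM and SEL1L from 27.2 to 20.4 FPKM, and SDF2L1 rose from 26.3 to 30.7 FPKM.

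Cholesterol synthesis genes rose, with 14 of 23 higher, 1 lower and 8 not past (14 and 1 adjusted over the list alone; camera adjusted p = 0.0024, adjusted p = 0.186 with an estimated correlation). INSIG1 rose 1.52-fold and MVK 1.34-fold, and LSS, lanosterol synthase, fell to a ratio of 0.807. This call ended without genes carrying the 3' UTR words (adjusted p = 0.19, in a range of 8.01e-06 to 0.19), where the median went from 0.19 over 23 members (bootstrap 95% interval 0.10 to 0.25) to 0.11 over 13 (0.06 to 0.20). Fatty acid synthesis gave 3 higher, 4 lower and 8 not past of 15 (3 and 4 adjusted over the list alone; camera adjusted p = 0.776), its median below 0 and its mean above 0, with ACSL4 up 1.82-fold and ELOVL1 at a ratio of 0.633. Lysosome and autophagy genes gave 10 higher, 6 lower and 10 not past of 26 (10 and 6 adjusted over the list alone; camera adjusted p = 0.776), with a median just above 0, a mean of -0.06 and a camera direction of down. The protease CTSK fell from 31.0 to 16.2 FPKM. Cytosolic ribosomal proteins gave 2 higher, 4 lower and 44 not past of 50 (1 and 3 adjusted over the list alone; camera adjusted p = 0.776), with RPS2 at a ratio of 0.796 and RPLP0 at 0.888.

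Markers of other cell types were low or did not rise as groups. PTPRC, the pan-leukocyte gene, was listed at 0 in all 6 libraries, and LYZ, the only immune marker measured, fell from 1.73 ± 0.152 to 0.914 ± 0.189 FPKM (n = 3, limma adjusted p = 0.00078). KRT10, the only keratinocyte marker measured, was at 20.6 ± 0.412 and 22.5 ± 2.66 FPKM (n = 3, limma adjusted p = 0.204). TIE1, the higher of 2 measured endothelial markers, was at 24.4 ± 0.78 and 22.9 ± 0.93 FPKM (n = 3, limma adjusted p = 0.137), and passed with quantile scaling (0.0381, in a range of 0.0381 to 0.35). Of 8 fibroblast markers 1 rose, 6 fell and 1 did not pass (1 and 7 adjusted over the list alone; camera adjusted p = 0.00943, adjusted p = 0.186 with an estimated correlation). COL1A2, COL1A1 and POSTN, which also stand on the matrix list, fell to ratios of 0.514, 0.716 and 0.703, and TWIST1 rose 1.33-fold. THY1, the most abundant of them, was at 28.5 ± 0.693 and 26.4 ± 1.22 FPKM (n = 3, limma adjusted p = 0.0819), and passed in 4 other settings, including without siPGC1a replicate 2 (0.0304), in a range of 0.0116 to 0.229.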

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

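Limma-voom on recovered reads and the list tests without genes carrying the 3' UTR words were chosen after seeing the data. The count of called genes, 5782 in the values as reported, ran from 4126 to 6379 over the other settings, and no called direction reversed, although the hypoxia median changed sign without genes carrying the words. PPARGC1A was lower and past the threshold in all of them. At a pseudocount of 0.1 FPKM 69 genes rose and 38 fell by at least 1 on the log2 scale, against 38 and 16, as a pseudocount of 1 FPKM shrinks the change of low genes. With limma-voom, which changes several choices at once, 77 and 48 did, and the cause was not tested. With a filter at a mean of 5 FPKM, which tests 7272 genes, 1607 genes were lower and 21 rose by at least 1. With an estimated inter-gene correlation camera called 0 lists, 0 higher and 0 lower, with 8 at an unadjusted p under 0.05. For some called lists the estimate lay above the preset 0.01, as for OXPHOS (0.373). For p53 targets (-0.007), cholesterol synthesis (0.005) and immediate early genes (0.008) it lay below. Yet their unadjusted camera p rose from 7.03e-05 to 0.0125, from 0.000974 to 0.026 and from 0.00064 to 0.0257. A higher correlation among members therefore did not end those calls. The p-values given with an estimated correlation thus do not measure correlation alone, and what else in that setting raised them was not tested. Camera on ranks called 20, and the cause was not tested. Fry, which tests a list against no change and not against other genes, called 25. Without genes that carry either 6-base word or lack a searched 3' UTR, 14 lists were called, 5 of them lower. That run tested 5279 genes and called 1839 higher and 886 lower, counts that the range of called genes above leaves out. Leaving out 1 library gave 4646 to 5366 called genes and 18 to 21 called lists. Of 113 named genes that passed, 111 passed in every setting that tested them, SDHA and CRYAB being the exceptions, and THY1 and TIE1 passed in some.

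The labels' replicate numbers were not shown to pair the samples: same-numbered libraries' deviations correlated at 0.077, 0.261 and -0.058, and not every library correlated best with its own number. With the replicate number as a block 6079 genes were called, 5665 of them shared with the fit without it, 3253 higher and 2826 lower, and the block ended the call of 1 list, the TGF-beta, BMP and ID targets (adjusted p = 0.0563).

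PPARGC1A rests on 97 to 117 reads in siPGC1a libraries, which limits the precision of its level.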

Other observations

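The tests of innate sensing, of regrouped samples for lists and of lists without genes holding the 3' UTR words were chosen after the result was seen, and the gene families in the next paragraph and the immune markers ITGAM, CD79A and CD68 were chosen after their values were seen.

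All 4 measured metallothionein genes, which bind zinc and copper, rose under the deposited scaling and under both other scalings. MT2A went from 53.4 ± 2.45 to 114.3 ± 4.07 FPKM and MT1E from 3.02 ± 0.305 to 7.36 ± 0.917 FPKM (n = 3, limma adjusted p = 4.23e-07 and 1.36e-05), and reads may be shared among these close copies. MHC class II transcripts were abundant, with HLA-DRA at 1982 ± 33.3 and 1894 ± 51.6 FPKM (n = 3, limma adjusted p = 0.131). Of 14 such genes 0 rose, 10 fell and 4 did not pass, among them CIITA, their transactivator, from 3.89 to 2.91 FPKM, and HLA-DOA from 89.2 to 63.0 FPKM. Under quantile scaling HLA-DRA instead rose (log2 fold change 0.11, limma adjusted p = 0.0492) and CD74 no longer passed (0.468). NRAS, chosen after its values were seen, fell from 17.8 ± 0.475 to 9.03 ± 0.588 FPKM (n = 3, limma adjusted p = 2.39e-06) and holds the word TACACCT once and ACACCT at 2 places in its 3' UTR.

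The fall of 2707 genes was weighed against miRNA-like repression through the siRNA's own seed, and of all 7-base words in the 3' UTRs of 10666 genes, TACACCT went most strongly with lower values (statistic -15.08, beyond -5.14 in 100 permutations, and 2.16 times the next word that shares no 6-base stretch with it, GTCTTCA), and it occurs in 14.1% of lower genes and 4.9% of the others. The median log2 fold change was 0.03, -0.12 and -0.15 for 0, 1 and 2 or more sites. Of 18 PPARGC1A transcripts 1 holds TACACCT, and how often a 7-base word occurs in such a transcript by chance was not tested. That transcript, the longest, of 6318 bases, holds it once, in its 3' UTR, within GGAAGACATGATACACCTA at bases 4756 to 4774. A seed effect of an siRNA aimed at that stretch is a candidate explanation for part of the falls, as a hypothesis, since the siRNA sequence is not known here, 843 of 2392 searched lower genes hold neither 6-base core, and loss of PGC1-alpha, which 1 siRNA cannot separate from its seed, stays open and untested. An effect of the opposite strand stays open. Its word TGTCTTC gave -4.89, short of the lowest permuted value of any word, -5.14, by less than its error. That tolerance was set after the value was seen. A limit over all words is stricter than 1 word fixed by the stretch needs, so -4.89 is not shown to lie within chance. GTCTTCA, which overlaps TGTCTTC by 6 bases, lay beyond the limit at -6.97 but was seen before the idea arose. A control siRNA seed stays open too. The highest word for the rises, TATTTAT, gave 5.94 with 3' UTR length, composition and expression in the model. That lies beyond the permutations at 4.88 but close to an unrelated word at 5.61. ATTTATT, which shares 6 bases with TATTTAT, gave 5.18. Without those covariates 33.7% of higher genes and 36.8% of the others hold TATTTAT. The medians were 0.02, 0.01 and -0.01 for 0, 1 and 2 or more sites. Yet 30 of the 50 largest rises hold it, against 18 expected. Whether TATTTAT marks a control siRNA seed or is held by these genes for another reason was not tested.

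The rise of OXPHOS and mitochondrial ribosomal protein genes, whose transcription PGC1-alpha is known to promote, was weighed against transcript length, GC content and scaling. The median log2 fold change of the 133 genes, 0.16, lay at percentile 99.91 of length-matched and at percentile 100 of GC-matched lists. The length-matched lists themselves had a median of 0.10, so short transcripts may account for part of the rise. The members' estimated inter-gene correlation was 0.373 for OXPHOS and 0.255 for mitochondrial ribosomal proteins. Matched genes need not share such a correlation, which makes the percentiles too extreme. They therefore cannot tell whether length or GC content accounts for all of the rise. The median of the 133 genes was 0.15 and 0.11 under the other 2 scalings, for which no matched lists were drawn. Reads shared with pseudogenes were not tested, and an effect of the siRNA's target stays open, untested.

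The rise of NF-kappaB and cytokine genes with lower interferon genes was weighed against immune sensing of the RNA and against immune cells. A stronger interferon response in the siPGC1a group would raise interferon genes, whose median instead fell by 0.34 (log2 fold change -0.37 to -0.162 over other settings). This test was chosen after that fall was seen. Both groups were transfected with siRNA, so sensing common to both would not show in the comparison. Sensing that leaves interferon genes unchanged would not show in this list, so sensing stays open. Immune cells would bring their abundant transcripts, but the 14 listed markers, of which LYZ alone passed the filter, averaged 0.343 and 0.322 FPKM (median change -0.002), with LYZ lower, PTPRC at 0 in all libraries, and ITGAM (0.506 to 0.776 FPKM), CD79A (0.147 to 0.242 FPKM) and CD68 (0.743 to 1.07 FPKM, the highest of the 14 in siPGC1a) higher in mean, while CXCL8 went from 2.45 to 14.4 FPKM. This argues against immune cells as the main source of the rise, though markers this low cannot exclude a small share of such cells. An effect of PGC1-alpha loss and a seed effect on a regulator stay open, untested.

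No conclusion on chance can be drawn from regrouping the samples, since 10 splits are too few for a share under 0.05. The real split was the 1 with as many called genes (5782, highest other 0 by limma, where 74 to 463 genes had an unadjusted p under 0.05) and the 1 with as many called lists (21, highest other 14). Without genes holding either 6-base core 13 of the 19 called lists that could be tested kept call and direction (the Wnt and fibroblast lists could not), where at least 14 of all 21 had been set as the mark against sites within the lists, so that a part of the sites in the lists' changes stays open. The 6 tested lists that lost their call went apart: the immediate early, integrated stress response and G2/M medians were 0.45, 0.22 and 0.14 without those genes against 0.43, 0.19 and 0.14, the cholesterol and TGF-beta medians shrank from 0.19 to 0.11 and from -0.12 to -0.06, and the hypoxia median went from -0.23 to 0.09. The intervals before and after overlapped for each of the 6, with fewer members after. As the members after are part of those before, this overlap cannot tell whether a median changed.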
